A study of Mus musculus with 18 samples.

How the data were processed

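Liver RNA from 18 male mice was measured on the Affymetrix Mouse Transcriptome Array 1.0, with 1 array per animal per the labels. About 100 mg of tissue per animal was ground in liquid nitrogen, RNA was extracted with an RNeasy mini kit, and biotin-labelled sense target was hybridised, per the labels' protocols. The labels name 6 groups of 3 arrays: HPNWT and EGFP livers at day 1, day 2 and day 4 of adeno-associated virus (AAV) transduction. The labels do not spell out HPNWT or say from which event the days were counted. The series' design text speaks of liver-specific overexpression of hepsin, a membrane serine protease encoded by Hpn. Because the arrays are 1 per animal, p-values of single genes rest on the spread between animals within the groups. The p-values of gene lists from the camera test described below compare a list with other genes. Under a preset correlation between genes they do not measure the spread between animals directly. No hybridisation date or batch was given in the sources used here.

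The deposited value table holds log2 expression values that the authors computed by robust multi-array averaging (RMA) in the Transcriptome Analysis Console, per the labels. Its version was not given in the submitters' processing notes. The table has 72688 rows, of which 6732 are control probe sets and 65956 are transcript clusters. The values range from 0.695 to 13.2. Gene symbols came from the authors' deposited comparison tables, which list the same cluster identifiers. A symbol was given for 40161 clusters, 3590 of which carry several symbols and are named nowhere in the text, and 25795 clusters had none. The comparison tables also hold, per the file headers, a group average on a log2 scale for HPNWT and for its control, a signed linear fold change used here as a score (negative where the control is higher, computed by the authors' software), a p-value and a false discovery rate (FDR) from the authors' own comparison at each day. The authors' deposited group averages span a wider range than the value table, from 2.24 to 19.9, and the software settings behind them were not given in the sources used here. Values from both sources are therefore never set side by side without their source, and a fold change from the value table is a difference on its RMA scale. Further deposited tables hold the lists of changed clusters. No genome was used.

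All comparisons were chosen before the data were examined. The 40161 clusters with a symbol were fitted in limma 3.58.1 (R 4.3.3, with statmod 1.5.0 and the data.table package at 1.17.8) with lmFit and eBayes. The fit had 6 group means over all 18 arrays, so that all groups shared 1 estimate of the spread. No further scaling, filter or covariate was applied. The differences HPNWT minus EGFP were tested at each day, the differences between these effects were tested for each pair of days, and a moderated F-test compared the 3 EGFP groups. The adjusted p is the Benjamini-Hochberg value over all clusters tested, and a gene was called changed under 0.05. Tests were 2-sided. Errors are standard errors (SE) from the fit or standard deviations (SD) of 3 arrays. The days do not share control arrays. The number of arrays limits the precision. In a comparison of 3 against 3 arrays an exact permutation test cannot go below p = 0.1, so single-day differences were tested only in limma.

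Before the data were examined, 44 gene lists for pathways, liver zones, other cell types and RNA quality were fixed, with 1138 genes, of which 1042 were matched by symbol and 62 stand in more than 1 list. A list needed at least 3 measured members, which left 43. Each of the 36230 single symbols was represented by its brightest cluster. The camera test of limma compared each list with all other genes under a preset correlation between genes of 0.01, with an estimated correlation and the fry test as alternatives. List p-values were adjusted over the 43 lists. Counts of changed members are given over all genes tested and adjusted over the list alone.

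The genes named were set by a rule. At each day these are Hpn, the 8 largest rises and 8 largest falls among genes that passed with no overlap between the 3 HPNWT and the 3 EGFP arrays, 3 members with the smallest p of up to 5 called lists, and 2 such members of each called list for another cell type. Across days they are the 6 genes with the largest mean change among those called the same way at all 3 days, and the 4 genes with the smallest p for each difference between days. Predicted genes, olfactory and vomeronasal receptors and small RNAs were counted and not named. They made up 200 of the 1141 non-overlapping rises and 223 of the 547 falls at day 1, 204 of 816 and 651 of 1236 at day 2, and 59 of 594 and 80 of 244 at day 4. A gene named outside the rule is said to be chosen after its values were seen. Results of 3 genes that these rules or counts include are not reported here.

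The gene test was tested on simulated arrays built for the day 1 comparison over 40161 clusters with 200 altered genes. It recovered 29 of 50 genes altered by 0.5 log2 (58%), all 50 altered by 1, all 50 altered by 1.5, all 25 altered by 2 and all 25 altered by 3, with 6 false calls. In the simulated day 4 comparison over 36230 symbols, a list of 25 genes shifted by 0.5 log2 was the 1 list called of 43. The simulated genes were drawn independently of each other, without arrays that stand apart. The simulation therefore does not show how often lists are called falsely where genes are correlated. Figures were drawn with matplotlib 3.10.9.

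Alternatives planned before the data were examined were a replicate block, a fit on the 6 arrays of a day, repeated quantile normalization over all rows, median centring, all transcript clusters, only clusters above the median mean level, eBayes with trend and robust settings, array quality weights, an unadjusted p under 0.05 with a fold of at least 1.5 or 2, an adjusted p under 0.1, camera with an estimated correlation, fry, the mean of all clusters of a gene, and each array left out. Added after seeing the data were the fit without both arrays that stand apart, the median of the negative-control probe sets as a covariate, and the FDR of the authors' tables. Random draws used a fixed seed.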

Results

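Gene expression was measured in 18 livers of male mice after AAV transduction. Livers labelled HPNWT and livers labelled EGFP, the green fluorescent protein control, were compared at day 1, day 2 and day 4, with 3 arrays in each of 6 groups. The series title asks about hepsin, epidermal growth factor receptor (EGFR) signalling and liver regeneration. Arrays were alike, with correlations between 0.982 and 0.998 and medians of the clusters with a symbol between 4.0 and 4.21 on the log2 scale, and no arrays held identical values. The principal components took 30.6%, 18.7% and 8.96% of the variance. HPNWT day 4 replicate 3 stood apart on the second (score 50.9) and HPNWT day 1 replicate 1 on the third (score −31.8). What the 5222 negative-control probe sets detect was not given in the sources used here. They had a lower median in HPNWT than in EGFP arrays at each day. The difference was −0.17 log2 at day 1 (3.04 ± 0.105 against 3.20 ± 0.0995, SD, n = 3), −0.37 at day 2 (3.04 ± 0.0526 against 3.41 ± 0.139) and −0.12 at day 4 (3.06 ± 0.160 against 3.18 ± 0.107). Their 95th percentile averaged 6.16 over the arrays, and where a group's mean lies under it the log2 differences below are differences of signal, given without a fold. An exact permutation test within days gave p = 0.00375 over 8000 relabellings with 3 arrays per group. The 23 background probe sets grouped by GC count moved the other way, by 0.10, 0.19 and 0.14 log2 (exact permutation p = 0.0035).

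**Figure D1:**
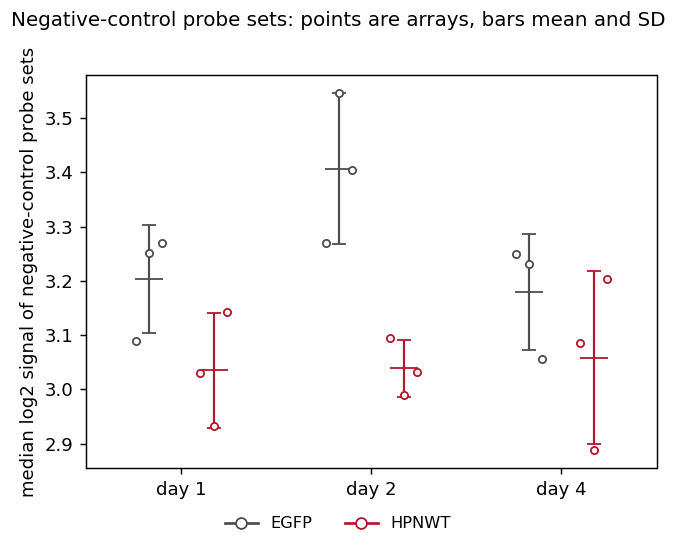
Median log2 signal of 5222 negative-control probe sets (vertical axis) for each array, by group and day; points are arrays and bars give the mean and SD of 3 arrays. The HPNWT means of 3.04, 3.04 and 3.06 lie below the EGFP means of 3.20, 3.41 and 3.18 at day 1, day 2 and day 4.

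Hpn, the mouse gene for hepsin, was not detectably higher in HPNWT livers. Its log2 signal was 8.26 ± 0.191 (SD, n = 3) in HPNWT and 8.32 ± 0.0877 in EGFP livers at day 1, 8.19 ± 0.0251 and 8.27 ± 0.0419 at day 2, and 8.30 ± 0.282 and 8.19 ± 0.107 at day 4. The differences were −0.06, −0.08 and 0.11 log2 (SE 0.12 each), with limma adjusted p = 0.894, 0.731 and 0.809. The sign turned at day 1 without HPNWT day 1 replicate 2 (0.02) and at day 4 without HPNWT day 4 replicate 3 (−0.06), and at day 2 after repeated quantile normalization (0.05). A transgene transcript that differs from the mouse probe sequences would not be seen by these probes, and the labels do not give its sequence. The groups below are therefore the livers labelled HPNWT and the livers labelled EGFP, and every direction is drawn from those labels alone, without a rise of Hpn behind it.

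At day 1, the rises in livers labelled HPNWT against livers labelled EGFP included Akr1c18, Egr1 and Angptl8, and the falls included Etnppl. Akr1c18, which encodes a hydroxysteroid dehydrogenase that inactivates progesterone, rose by 3.52 log2 (SE 0.24, 3 arrays per group) from an EGFP mean of 3.89. The immediate early transcription factor Egr1 rose by 2.73 (SE 0.26, 6.64-fold), and Angptl8, a secreted inhibitor of lipoprotein lipase, by 2.63 (SE 0.52). The interferon-inducible Ifi27l2b rose by 2.52, the peroxisomal very-long-chain acyl-CoA transporter Abcd2 by 2.38, the cytochrome P450 Cyp2b9 by 2.15, the basement membrane gene Nid1 by 2.11 and Tnfrsf12a, the receptor for the cytokine TWEAK, by 2.08. Falls were seen for the pseudogene Gtpbp4-ps1 (−3.64, SE 0.53, to an HPNWT mean of 3.21) and Etnppl, an enzyme that degrades phosphoethanolamine (−2.57, SE 0.33). They were followed by the pseudogene Gtpbp4-ps4 (−1.81), Glt1d1 (−1.73), the pseudogene Marcksl1-ps4 (−1.68), the aldo-keto reductase Akr1c19 (−1.59), the aromatic amino acid decarboxylase Ddc (−1.55) and the pseudogene Obox4-ps3 (−1.49). The EGFP means of Akr1c18, Abcd2, Cyp2b9 and Tnfrsf12a and the HPNWT means of all falling genes but Ddc lay under 6.16, so the order among them is not exact. For these 16 genes all 3 HPNWT arrays lay on 1 side of all 3 EGFP arrays, and limma adjusted p ran from 4.3e-06 (Akr1c18) to 0.0115 (Ddc). Ddc did not pass without HPNWT day 1 replicate 1 (adjusted p = 0.0600), HPNWT day 1 replicate 2 (0.0612), EGFP day 1 replicate 2 (0.0654) or EGFP day 1 replicate 3 (0.0587), nor in the fit on the 6 arrays of that day (0.0811). In all, 1194 genes were higher and 649 lower of 40161 tested, 95 and 71 of them by at least 2-fold, and 6326 had an unadjusted p under 0.05. Of all clusters tested, 18.3% had no overlap between the groups, where chance gives 10%. After median centring the split was 1268 higher and 391 lower. The total of 1843 was 953, 858 and 2993 without HPNWT day 1 replicate 1, 2 and 3, and 1192, 1015 and 1078 without EGFP day 1 replicate 1, 2 and 3. It was 723 from the 6 arrays of that day and 8116 with array quality weights.

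Cholesterol biosynthesis was the list that differed most from other genes at day 1. Of its 25 measured members 19 rose and none fell over all genes, 20 and 0 adjusted over the list alone, with a median difference of 0.98 log2 (camera adjusted p = 2.8e-24, and adjusted p = 0.127 with an estimated correlation). Lanosterol synthase (Lss) rose by 1.74 (SE 0.20), mevalonate kinase (Mvk) by 1.38 (SE 0.15) and Dhcr7, the reductase of a final step, by 1.26 (SE 0.11). In the unfolded protein response list of 29 genes 12 rose and none fell, 17 and 0 adjusted over the list alone, with a median of 0.40 (adjusted p = 1.5e-13). This was the 1 list of day 1 that held with an estimated correlation (adjusted p = 0.0176). It included the disulfide isomerase Pdia6 (0.72), the translocon subunit Sec61b (0.68) and the chaperone cofactor Dnajb11 (0.73). Ribosome biogenesis genes rose in 9 of 34 cases, 19 with 1 fall adjusted over the list alone, including the nucleolar genes Tsr1 (0.54), Mybbp1a (0.58) and Lyar (0.32). The adjusted p was 2.0e-11, and adjusted p = 0.289 with an estimated correlation. Ribosomal protein genes had a median of 0.19 (adjusted p = 3.8e-09, and adjusted p = 0.404 with an estimated correlation), with Rpl3 (0.56) and Rps6 (0.29) the 2 called of 40, 9 adjusted over the list alone, and Rpsa at 0.44 (limma adjusted p = 0.0535). Rps6 kept its call only without HPNWT day 1 replicate 1 or 3, EGFP day 2 replicate 2 or 3, or HPNWT day 4 replicate 2 or 3, and otherwise its limma adjusted p ran from 0.0506 to 0.212 with an array left out. In the fit on the 6 arrays of that day Lyar (limma adjusted p = 0.109), Rpl3 (0.0519) and Rps6 (0.200) did not pass.

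The bile acid and drug metabolism lists were lower at day 1 by camera, but not with an estimated correlation, and most members were not called. In the list of bile acid synthesis and transport 6 of 27 members fell and none rose, 10 and 1 adjusted over the list alone, with a median of −0.32 (adjusted p = 1.0e-05, and adjusted p = 0.229 with an estimated correlation). Akr1d1, the steroid 5β-reductase of bile acid synthesis, fell by 1.13 on the log2 scale (SE 0.13), and the organic anion uptake transporters Slco1b2 and Slco1a4 fell by 0.90 (SE 0.18) and 1.26 (SE 0.28). Slco1a4 did not pass without HPNWT day 1 replicate 2 (limma adjusted p = 0.0716) or in the fit on the 6 arrays of that day (0.146). Among 38 drug metabolism genes, Fmo1 (−0.52) and Cyp3a25 (−0.67) fell and Cyp2b9 rose, 9 fell and 1 rose adjusted over the list alone, and the median was −0.23 (adjusted p = 2.5e-05, and adjusted p = 0.127 with an estimated correlation). Fmo1 and Cyp3a25 were named after their values were seen. Among 30 male-biased liver genes regulated by STAT5, the transcription factor of growth hormone signalling, Igfals (−1.30), Nudt7 (−1.14) and Ghr (−0.58) fell and Serpina12 (1.21) rose, named here after their values were seen. Adjusted over the list alone 5 fell and 1 rose, and the median was −0.21 (adjusted p = 4.3e-04, and adjusted p = 0.378 with an estimated correlation). That list did not pass without HPNWT day 1 replicate 1 (adjusted p = 0.0580).

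Lists of cell-cell contact and early response were higher at day 1 by camera, but not with an estimated correlation. In the list of connexins and junctions Cldn14 (0.75), Cdh1 (0.96), F11r (0.49) and Cldn1 (1.06), all junction proteins, rose and none of 18 fell (6 and 0 adjusted over the list alone; adjusted p = 4.5e-04, and adjusted p = 0.127 with an estimated correlation). These 4 were named after their values were seen. Of 28 immediate early genes 6 rose, 9 adjusted over the list alone (median 0.05; adjusted p = 0.0044, and adjusted p = 0.289 with an estimated correlation), and the list did not pass without HPNWT day 1 replicate 3 (adjusted p = 0.0864). For the EGFR pathway that the title names, the list of 38 ligands, receptors and feedback genes of EGFR and the hepatocyte growth factor (HGF) receptor had a median of 0.13 (adjusted p = 0.0230, and adjusted p = 0.420 with an estimated correlation). The feedback phosphatase Dusp5 (1.5), the transcription factor Etv5 (0.70), the adaptor Shc1 (0.58) and Hgfac, the protease that activates HGF (0.50), rose, and Met, the HGF receptor, fell (−0.31), all named after their values were seen. Adjusted over the list alone 5 rose and 1 fell, and after median centring the list did not pass (adjusted p = 0.0566).

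Kupffer cell, periportal, pericentral, gluconeogenesis and clock lists were lower at day 1 by camera. The Kupffer cell and macrophage list had a median of −0.22 with none of its 19 members called over all genes or adjusted over the list alone (adjusted p = 4.8e-04, and adjusted p = 0.569 with an estimated correlation). With the negative-control covariate it did not pass (adjusted p = 0.0725), and the gluconeogenesis list did not either (0.223). The iron exporter Slc40a1 was at −0.55 (limma adjusted p = 0.0706) and Mpeg1, a macrophage perforin, at 0.81 (0.116). Of 27 periportal genes 6 fell and 1 rose, 8 and 3 adjusted over the list alone (median −0.12; adjusted p = 4.8e-04, and adjusted p = 0.378 with an estimated correlation). Of 24 pericentral genes 3 fell and 2 rose, 5 and 3 adjusted over the list alone (median −0.21; adjusted p = 0.00421, and adjusted p = 0.314 with an estimated correlation). The gluconeogenic enzymes Fbp1 (−0.47) and Pck1 (−0.79) were the 2 called of 17, both falling, with 3 adjusted over the list alone (median −0.25; adjusted p = 5.5e-04, and adjusted p = 0.337 with an estimated correlation). Of 25 circadian clock genes 2 fell over all genes and adjusted over the list alone, among them Usp2 (−1.25; list median −0.21; adjusted p = 0.0293, and adjusted p = 0.377 with an estimated correlation). Fbp1, Pck1 and Usp2 were named after their values were seen. The gluconeogenesis median ran from −0.34 to −0.11 with 1 array left out. The clock list did not pass without HPNWT day 1 replicate 3, with a median of 0.02 (adjusted p = 0.366). In all, 15 of 43 lists passed, 7 higher and 8 lower, and fry called 7 of the 43. Camera called up to 16 lists when the 6 arrays of that day were split otherwise.

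At day 2, Akr1c18, Cyp2b9, Ifi27l2b, Abcd2 and Angptl8 were again among the rises in livers labelled HPNWT. Akr1c18 rose by 5.12 log2 (SE 0.24, 3 arrays per group) from an EGFP mean of 3.87, Cyp2b9 by 3.61 (SE 0.36) from 4.24, Ifi27l2b by 3.04, Abcd2 by 2.88 and Angptl8 by 2.78. The proton pump subunit Atp6v0d2 rose by 2.72 and Slc10a2, a sodium-dependent bile acid transporter, by 2.24. Falls were seen for Gtpbp4-ps1 (−2.97), Csad, an enzyme of taurine synthesis (−2.72, SE 0.33), and Etnppl (−2.23). Obox4-ps3 (−2.22), the glucose-6-phosphatase gene G6pc (−2.12, SE 0.57), Gtpbp4-ps4 (−2.01), the ornithine aminotransferase Oat (−1.98, SE 0.17) and the fatty acid elongase Elovl3 (−1.87) followed. The EGFP means of Akr1c18, Cyp2b9, Abcd2 and Atp6v0d2 and the HPNWT means of Csad and the pseudogenes lay under 6.16, so the order among them is not exact. All of these had no overlap between the 3 HPNWT and 3 EGFP arrays, with limma adjusted p from 1.35e-08 (Akr1c18) to 0.0388 (G6pc). G6pc passed in no fit without 1 of the day 2 arrays (adjusted p = 0.0570, 0.1 and 0.133 without HPNWT replicate 1, 2 and 3, and 0.101, 0.133 and 0.0815 without EGFP replicate 1, 2 and 3). Elovl3 did not pass without HPNWT day 2 replicate 2 (0.0552) or 3 (0.0517) or EGFP day 2 replicate 1 (0.0567) or 2 (0.0605).

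Of 40161 genes 869 were higher and 1408 lower at day 2, 82 and 152 of them by at least 2-fold, and 7993 had an unadjusted p under 0.05. No overlap was seen for 34.3% of clusters, where chance gives 10%. Which direction prevailed depended on the scaling, since repeated quantile normalization gave 2204 higher and 1027 lower (68.2% higher, against 38.2% as reported). The total of 2277 was 1371, 932 and 1329 without HPNWT day 2 replicate 1, 2 and 3, 791 and 1028 without EGFP day 2 replicate 2 and 3, and 3487 without HPNWT day 4 replicate 3. The negative-control difference was largest at this day, and with that median as a covariate, chosen after seeing the data, 71 genes were higher and 16 lower. Of the 2277 genes, 2272 kept their sign, the median share of the difference left was 75.0% (quartiles 51.9% and 95%), and the median SE was 1.48 times as large, so calls ended through wider errors as well as smaller differences. Differences stayed near their size with wider errors for Slc10a2 (2.31, SE 0.50; limma adjusted p = 0.0852) and Gtpbp4-ps4 (−1.92, SE 0.51; 0.212). They were smaller for Atp6v0d2 (2.23, SE 0.51; 0.108), Csad (−2.13, SE 0.46; 0.0909), Angptl8 (2.13, SE 0.78; 0.472), Gtpbp4-ps1 (−1.82, SE 0.73; 0.513) and Etnppl (−1.68, SE 0.48; 0.263). Elovl3 (−1.13, SE 0.59; 0.675) and G6pc (−0.68, SE 0.74; 0.871) did not pass either. Akr1c18, Cyp2b9, Ifi27l2b, Abcd2, Obox4-ps3 and Oat passed in that fit.

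DNA replication genes rose as a group at day 2 by camera, but not with an estimated correlation. Of 43 S phase genes 19 rose and none fell, 33 and 3 adjusted over the list alone, with a median of 0.26 log2 (camera adjusted p = 9.5e-14, and adjusted p = 0.0995 with an estimated correlation). The replicative helicase subunits Mcm6, Mcm4 and Mcm2 rose by 1.40 (SE 0.13), 1.10 (SE 0.13) and 0.94 (SE 0.13). Of 49 G2/M and mitosis genes, the mitotic kinase Nek2 (0.33) and the checkpoint gene Mad2l1 (0.40) were the 2 called, both rising and named after their values were seen, with 3 adjusted over the list alone (median 0.15; adjusted p = 1.4e-04, and adjusted p = 0.804 with an estimated correlation). Cholesterol biosynthesis genes rose in 6 of 25 cases, 13 with 1 fall adjusted over the list alone (median 0.47; adjusted p = 3.95e-07, and adjusted p = 0.453 with an estimated correlation), among them Dhcr7 (1.01) and the squalene epoxidase Sqle (1.32). The cholesterol median ran from 0.23 to 0.65 with 1 array left out. Of 29 unfolded protein response genes 10 rose, 14 adjusted over the list alone (adjusted p = 1.4e-06, and adjusted p = 0.0995 with an estimated correlation). With the negative-control median as a covariate the differences of Mcm2 (0.97, SE 0.21; limma adjusted p = 0.0790) and Sqle (1.86, SE 0.37; 0.0579) were no smaller, but with wider errors they did not pass. The EGFP and HPNWT means of the 3 Mcm genes lay under 6.16.

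Liver-specific metabolic lists were lower at day 2 by camera, but not with an estimated correlation. Bile acid genes fell in 6 of 27 cases, 13 adjusted over the list alone (median −0.42; adjusted p = 5.4e-08, and adjusted p = 0.0995 with an estimated correlation), including the sterol 27-hydroxylase Cyp27a1 (−0.97), Akr1d1 (−0.80) and Slco1b2 (−1.0). Of 24 pericentral genes 8 fell and 2 rose, also adjusted over the list alone (median −0.28; adjusted p = 3.95e-07, and adjusted p = 0.0995 with an estimated correlation), with Oat, Cyp27a1 and the glutamate transporter Slc1a2 (−1.17) lowest in p. Male-biased genes fell in 8 of 30 cases with no rise, 11 and 2 adjusted over the list alone (median −0.38; adjusted p = 3.95e-07, and adjusted p = 0.234 with an estimated correlation), including the peroxisomal hydrolase Nudt7 (−1.02), the growth hormone receptor Ghr (−0.55) and Igfals, a carrier of insulin-like growth factors (−0.84). Drug metabolism genes fell in 6 of 38 cases while Cyp2b9 and the related Cyp2b13 (1.12, named after its value was seen) rose, 11 and 4 adjusted over the list alone (adjusted p = 6.6e-04, and adjusted p = 0.234 with an estimated correlation). The list of oxidative stress genes regulated by NRF2 was lower too (5 fell and 1 rose of 27, 8 and 3 adjusted over the list alone; adjusted p = 0.00593, and adjusted p = 0.716 with an estimated correlation). The 5 that fell were Sod2 (−0.44), Aox1 (−1.16), Ugdh (−0.87), Ephx1 (−0.35) and Gclm (−0.37), and the 1 that rose was G6pdx (1.33), named after their values were seen. Of 17 gluconeogenesis genes G6pc was the 1 called, with 4 falling adjusted over the list alone (median −0.27; adjusted p = 7.6e-05, and adjusted p = 0.264 with an estimated correlation). The gluconeogenesis median was 0.05 with the negative-control covariate, where the NRF2 list did not pass (−0.11, adjusted p = 0.434). In that fit Slco1b2 (−1.26, SE 0.27), Slc1a2 (−1.30, SE 0.29) and Ghr (−0.59, SE 0.14) had differences no smaller than before and Akr1d1 (−0.73, SE 0.20), Cyp27a1 (−0.73, SE 0.16), Nudt7 (−0.77, SE 0.21) and Igfals (−0.59, SE 0.23) smaller ones, and with wider errors none passed (limma adjusted p from 0.0783 to 0.513).

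Kupffer cell markers were lower at day 2 on balance by camera, with opposite moves inside the list. Of 19 markers Ctss, a lysosomal protease (−0.58), and Slc40a1 (−0.65, named after its value was seen) fell and Mpeg1 rose (1.41), and 10 fell and 1 rose adjusted over the list alone (median −0.35; adjusted p = 3.7e-06, and adjusted p = 0.452 with an estimated correlation). Ctss did not pass without HPNWT day 2 replicate 1 (limma adjusted p = 0.0503) or 2 (0.0973) or EGFP day 2 replicate 1 (0.0632) or 3 (0.0727). With the negative-control covariate the list median was −0.14 and the list did not pass (adjusted p = 0.110), nor did Ctss (−0.44, SE 0.20; limma adjusted p = 0.595) and Mpeg1 (1.22, SE 0.42; 0.413). The gallbladder and gut list (median 0.10; adjusted p = 0.0357, and adjusted p = 0.296 with an estimated correlation) held 2 rises among 13 genes, also adjusted over the list alone. These were the apolipoprotein Apoa4 (1.62), which hepatocytes also express, and the mucosal peptide Tff3 (1.59). Tff3 did not pass without HPNWT day 2 replicate 1 (0.0593) or 2 (0.0858) or EGFP day 2 replicate 2 (0.0868) or 3 (0.0506), nor with the covariate at a larger difference (1.92, SE 0.55; 0.263). The gallbladder and gut list did not pass with the covariate (0.248) or without HPNWT day 2 replicate 2 (0.102) or EGFP day 2 replicate 3 (0.0566). Immediate early genes rose in 5 of 28 cases, 9 adjusted over the list alone (adjusted p = 0.0139, and adjusted p = 0.296 with an estimated correlation), namely Atf3 (0.83), Egr1 (1.28), Btg2 (1.0), Ier2 (0.52) and Gadd45b (0.89), and the list did not pass without HPNWT day 2 replicate 1 (0.0555). Junction genes rose in 3 of 18 cases, Cldn14 (0.74), F11r (0.48) and Cdh1 (0.76), and 5 rose and 1 fell adjusted over the list alone (adjusted p = 0.0139, and adjusted p = 0.286 with an estimated correlation). Genes listed in the last 2 sentences were named after their values were seen.

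Sinusoidal endothelial, heat shock and PPARα lists were lower at day 2 by camera, with few or no members called. The sinusoidal endothelial list had a median of −0.10 with none of 21 genes called over all genes or adjusted over the list alone (adjusted p = 0.0139, and adjusted p = 0.796 with an estimated correlation). The scavenger receptor Stab2 and the Wnt agonist Rspo3 were at −0.36 each (limma adjusted p = 0.209 and 0.220). The list did not pass without HPNWT day 2 replicate 2 (0.187), and its median was 0.14 with the negative-control covariate. The heat shock list (median −0.12, no member called of 17 over all genes or adjusted over the list alone; adjusted p = 0.0259, and adjusted p = 0.796 with an estimated correlation) did not pass without HPNWT day 2 replicate 2 (0.133) or EGFP day 2 replicate 1 (0.173). The list for PPARα, the receptor that drives fatty acid oxidation, had 3 falls among 36 genes, Cpt2 (−0.54), Acaa1b (−0.70) and Cyp4a32 (−1.08), named after their values were seen. Adjusted over the list alone 4 fell and 1 rose (adjusted p = 0.00964, and adjusted p = 0.804 with an estimated correlation), and the list did not pass without HPNWT day 2 replicate 2 (0.146) or EGFP day 2 replicate 3 (0.0566). With the negative-control covariate the PPARα list did not pass (median 0.00151, adjusted p = 0.976). After repeated quantile normalization the PPARα median was 0.01 and the PPARα, sinusoidal, heat shock and gallbladder lists did not pass (adjusted p = 0.0841, 0.0999, 0.159 and 0.0721). The EGFR and HGF list did not pass at day 2 (median 0.10; 4 rose and 1 fell, 4 and 5 adjusted over the list alone; adjusted p = 0.428). Its members Hgfac (0.90), Dusp5 (1.29), Etv5 (0.54) and Mst1r (0.50) rose and Hgf fell (−0.70), named after their values were seen. In all, 17 of 43 lists passed, 7 higher and 10 lower, none held with an estimated correlation, and fry called 10 of the 43. Camera called up to 18 lists when the 6 arrays of that day were split otherwise.

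At day 4, mitotic and interferon-stimulated genes were among the rises in livers labelled HPNWT, and Saa1, Saa2, Cyp4a12a and Cyp4a12b were among the falls. Akr1c18 rose by 5.79 log2 (SE 0.24, 3 arrays per group) from an EGFP mean of 3.92, Cyp2b9 by 4.80 (SE 0.36) from 4.17, the cornified envelope gene Sprr1a by 3.35 from 3.15 and Rgs16, a regulator of G protein signalling, by 3.28. Abcd2 rose by 3.11, Ifi27l2b by 2.93, the interferon-induced Ifi44 by 2.43 and the proliferation marker Mki67 by 2.34 from 3.01. The serum amyloid genes Saa2 and Saa1, secreted in inflammation, also had large falls (−3.77, SE 0.44, 13.7-fold lower, and −3.58, SE 0.39). Elovl3 (−2.90), the male-biased fatty acid hydroxylases Cyp4a12b (−2.90) and Cyp4a12a (−2.66), Gtpbp4-ps1 (−2.76), Csad (−2.63) and G6pc (−2.27, SE 0.57) fell too. The EGFP means of Akr1c18, Cyp2b9, Sprr1a, Abcd2, Ifi44 and Mki67 and the HPNWT mean of Gtpbp4-ps1 lay under 6.16, those of Sprr1a and Mki67 no higher than the negative-control median, so the order among them is not exact. All 16 had no overlap between the 3 HPNWT and 3 EGFP arrays, with limma adjusted p from 2.0e-09 (Akr1c18) to 0.0496 (G6pc). G6pc kept its call only without HPNWT day 1 replicate 1 or 3, EGFP day 1 replicate 1 or HPNWT day 4 replicate 3, and otherwise its limma adjusted p ran from 0.0531 to 0.183 with an array left out. Gtpbp4-ps1 did not pass without EGFP day 4 replicate 2 (0.0535). In the fit on the 6 arrays of that day, Rgs16 (0.164), Ifi44 (0.106), Mki67 (0.0580), Cyp4a12a (0.0860), Csad (0.0644) and G6pc (0.160) did not pass, nor did, of the genes named for day 4 below, Ccna2 (0.0533), Oas1a (0.0889), Mcm2 (0.0793), Pdia6 (0.0526), Ddit3 (0.114), Cyp27a1 (0.0540), Reln (0.167), Ly6c2 (0.281), Etnppl (0.144) and Irf7 (0.0889). Of 40161 genes 620 were higher and 269 lower, 101 and 45 of them by at least 2-fold, and 4904 had an unadjusted p under 0.05. No overlap was seen for 15.6% of clusters, where chance gives 10%. The total of 889 was 528 and 591 without EGFP day 4 replicate 1 and 2, 149 from the 6 arrays of that day and 2363 with array quality weights.

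Cell cycle genes rose as a group at day 4. Of 49 G2/M and mitosis genes 39 rose and none fell, 44 and 0 adjusted over the list alone, with a median of 0.53 log2 (camera adjusted p = 2.5e-54, and adjusted p = 0.0268 with an estimated correlation). The cyclins Ccnb2 and Ccna2 rose by 2.02 (SE 0.19) and 0.98 (SE 0.11), beside Mki67, from EGFP means of 3.77 and 3.31 to HPNWT means of 5.79 and 4.29, under 6.16 in both groups. The SD of Ccnb2, Ccna2 and Mki67 was larger in HPNWT (0.599, 0.292 and 0.829) than in EGFP arrays (0.0444, 0.0842 and 0.0239). The SE rests on the spread shared by all groups and does not show this. Of 43 S phase genes 16 rose and none fell, 27 and 0 adjusted over the list alone (median 0.25; adjusted p = 4.6e-24, and adjusted p = 0.00976 with an estimated correlation), with Mcm6 at 1.53, Mcm4 at 1.03 and Mcm2 at 0.95 (SE 0.13 each). HPNWT day 4 replicate 3 stood apart, and without it the G2/M median was 0.39 and 37 members were called. Of 19 G1 cyclins and cell cycle inhibitors Rbl1 rose (0.69), 5 rose and 1 fell adjusted over the list alone (adjusted p = 0.00875, and adjusted p = 0.332 with an estimated correlation), and the list did not pass without HPNWT day 4 replicate 3 (0.188). Among 27 p53 targets Psrc1 (1.12) and Tnfrsf10b (0.65) rose, 5 adjusted over the list alone (adjusted p = 0.00601, and adjusted p = 0.445 with an estimated correlation), and this list did not pass without that array either (0.213). Rbl1, Psrc1 and Tnfrsf10b were named after their values were seen.

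Interferon-stimulated genes rose at day 4. Of 47 members 28 rose and none fell, 38 and 0 adjusted over the list alone, with a median of 0.58 log2 (camera adjusted p = 3.7e-42, and adjusted p = 0.00976 with an estimated correlation). The RNA sensor Ddx58 rose by 0.65 (SE 0.08), the antiviral synthetase Oas1a by 0.95 (SE 0.12) and Ifi27l2a by 0.66 (SE 0.09). The means of Oas1a and Ifi27l2a lay under 6.16 in both groups, and that of Ddx58 in EGFP livers (6.01). The list median was −0.05 at day 1 and 0.02 at day 2 and did not pass there (adjusted p = 0.507 and 0.630), and at day 2 the test pointed lower while median and mean were above 0. Of 16 antigen presentation genes Psmb8 (0.55), H2-T23 (0.60) and H2-Q4 (0.31) rose, named after their values were seen, and 6 adjusted over the list alone (adjusted p = 5.7e-05, and adjusted p = 0.233 with an estimated correlation). Acute phase genes fell in 5 of 31 cases, 8 with 2 rises adjusted over the list alone (median −0.18; adjusted p = 3.8e-05, and adjusted p = 0.332 with an estimated correlation). Besides Saa1 and Saa2 these were the lipopolysaccharide-binding protein gene Lbp (−1.35) and the orosomucoid genes Orm1 (−0.46) and Orm2 (−1.98), named after their values were seen. The acute phase median ran from −0.25 to −0.10 with 1 array left out.

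The unfolded protein response and liver zonation lists also moved at day 4. Of 29 unfolded protein response genes Pdia6 (0.63), the stress-induced transcription factor Ddit3 (1.90), its target Trib3 (1.07) and the kinase Eif2ak3 (0.53, named after its value was seen) rose, and 9 adjusted over the list alone (median 0.33; adjusted p = 8.2e-14, and adjusted p = 0.00895 with an estimated correlation). Of 24 pericentral genes 7 fell and none rose, 11 and 0 adjusted over the list alone, with a median of −0.42 (adjusted p = 2.4e-13, and adjusted p = 0.00895 with an estimated correlation). The pericentral median ran from −0.49 to −0.25 with 1 array left out. Oat fell by 2.21 (SE 0.17), Slc1a2 by 2.04 (SE 0.19) and Cyp27a1 by 0.87 (SE 0.12). Bile acid genes fell in 3 of 27 cases, Cyp27a1, Cyp7b1 (−1.66) and Slco1b2 (−0.88), and 8 fell and 1 rose adjusted over the list alone (median −0.29; adjusted p = 5.5e-06, and adjusted p = 0.109 with an estimated correlation). Cyp7b1 and Slco1b2 were named here after their values were seen.

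In these male livers, some male-biased genes fell and some female-biased genes rose at day 4. Of 30 male-biased genes 7 fell and none rose, 12 and 2 adjusted over the list alone (median −0.38; adjusted p = 1.9e-10, and adjusted p = 0.0767 with an estimated correlation). Of 32 female-biased genes 8 rose and none fell, 9 and 0 adjusted over the list alone (median 0.08, mean 0.57; adjusted p = 2.8e-05, and adjusted p = 0.103 with an estimated correlation), led by Cyp2b9 and Abcd2. At day 1 the female-biased list did not pass (adjusted p = 0.713), with a median of −0.02 and a mean of 0.21 of opposite sign, and at day 2 it did not pass either (adjusted p = 0.1). Among 38 drug metabolism genes 6 fell and 4 rose, 10 and 6 adjusted over the list alone (median −0.18; adjusted p = 0.0061, and adjusted p = 0.233 with an estimated correlation). The 4 were Cyp2b9, Cyp2b13 (1.72), Cyp2b10 (1.17) and the estrogen sulfotransferase Sult1e1 (0.34). The drug metabolism median ran from −0.18 to −0.088 with 1 array left out. Of 17 gluconeogenesis genes G6pc was the 1 called, 2 fell and 1 rose adjusted over the list alone (median −0.19; adjusted p = 0.0084, and adjusted p = 0.344 with an estimated correlation), and the list did not pass without HPNWT day 4 replicate 1 (0.138) or 2 (0.120) or EGFP day 4 replicate 2 (0.0832), or with the negative-control covariate (0.314). Cyp2b13, Cyp2b10 and Sult1e1 were named after their values were seen.

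Growth factor, early-response and junction lists were higher at day 4 by camera, but not with an estimated correlation. Of 38 EGFR and HGF genes Hgfac (1.18), the EGFR ligand betacellulin (Btc, 0.65) and Dusp5 (0.94) rose and none fell, 7 and 1 adjusted over the list alone (median 0.15; adjusted p = 0.00311, and adjusted p = 0.233 with an estimated correlation). Without HPNWT day 4 replicate 3 this list did not pass (median 0.05, adjusted p = 0.128). Immediate early genes Atf3 (1.17), Egr1 (1.29) and Ier2 (0.64) rose of 28, 10 adjusted over the list alone (median 0.23; adjusted p = 3.1e-05, and adjusted p = 0.0566 with an estimated correlation). The junction genes F11r (0.67), Cdh1 (0.89) and Cldn14 (0.42) rose of 18, also 3 adjusted over the list alone (adjusted p = 7.1e-04, and adjusted p = 0.0836 with an estimated correlation). Of 27 glycolysis and glycogen genes none was called over all genes and 4 rose adjusted over the list alone (median 0.17; adjusted p = 5.95e-05, and adjusted p = 0.154 with an estimated correlation). All genes of this paragraph were named after their values were seen.

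Marker lists of other cell types moved little at day 4. Stellate cell and fibroblast markers had a median of 0.15 with Reln, an extracellular matrix protein (0.74), the 1 called of 19 also adjusted over the list alone, and the contractile gene Tagln at 0.58 (limma adjusted p = 0.200). The list passed by camera (adjusted p = 0.00653, and adjusted p = 0.568 with an estimated correlation), but its median was −0.03 without HPNWT day 4 replicate 3. Cholangiocyte markers had none of 15 called, 3 adjusted over the list alone (median 0.11; adjusted p = 0.0268, and adjusted p = 0.233 with an estimated correlation), with the bile duct surface proteins Tspan8 at 0.47 (limma adjusted p = 0.0777) and Epcam at 0.35 (0.118). They did not pass without HPNWT day 4 replicate 3 (0.111) or EGFP day 4 replicate 2 (0.146). Of 12 monocyte markers the surface antigen gene Ly6c2 rose (0.71), also adjusted over the list alone, and Ms4a4c was at 0.26 (limma adjusted p = 0.191; list adjusted p = 0.0405, and adjusted p = 0.325 with an estimated correlation). That list did not pass without HPNWT day 4 replicate 3 (0.273) or EGFP day 4 replicate 3 (0.182), and Ly6c2 did not without HPNWT day 4 replicate 2 (0.0938) or EGFP day 4 replicate 3 (0.0945). In all, 21 of 43 lists passed at day 4, 15 higher and 6 lower, 5 held with an estimated correlation, and fry called 16 of the 43. Camera called up to 23 lists when the 6 arrays of that day were split otherwise.

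**Figure D2:**
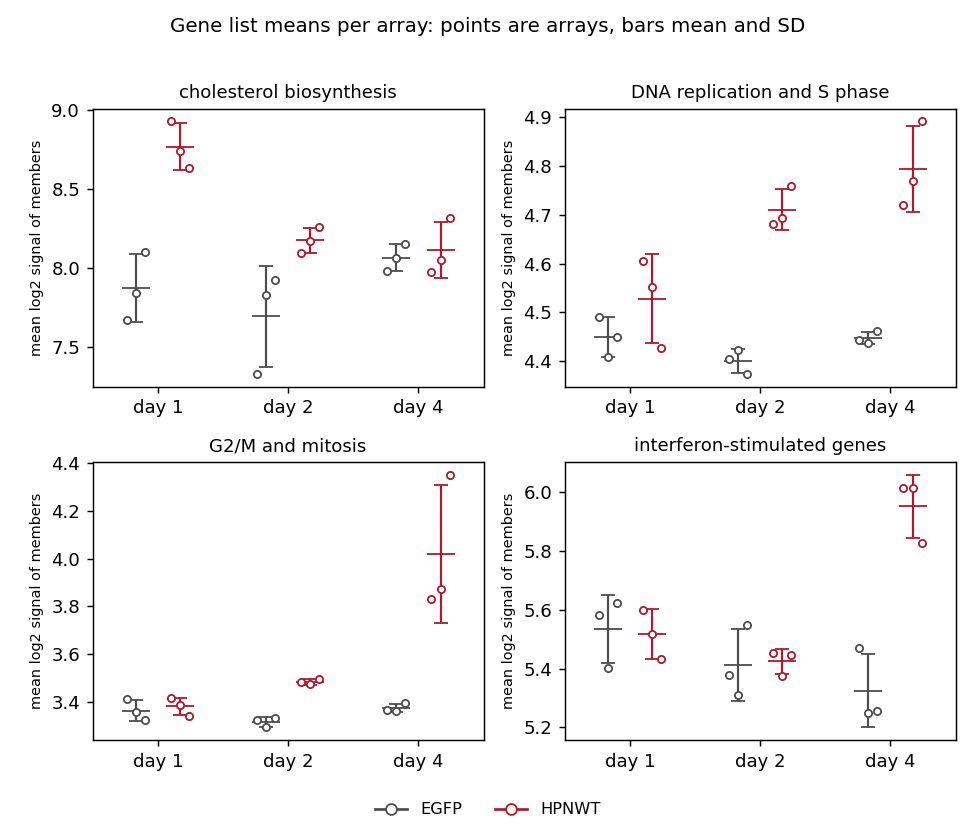
Mean log2 signal of the members of 4 gene lists (vertical axes) for each array, by group and day; points are arrays and bars give the mean and SD of 3 arrays. Median differences were 0.98 log2 at day 1 for cholesterol biosynthesis, 0.26 at day 2 for DNA replication, and 0.53 and 0.58 at day 4 for mitosis and interferon-stimulated genes.

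Genes that moved the same way at all 3 days included Akr1c18, Cyp2b9, Gtpbp4-ps1, Ifi27l2b, Abcd2 and Etnppl. Akr1c18 differed by 3.52, 5.12 and 5.79 log2 at day 1, day 2 and day 4 and Cyp2b9 by 2.15, 3.61 and 4.80, always with the arrays labelled HPNWT higher. Ifi27l2b (2.52, 3.04 and 2.93) and Abcd2 (2.38, 2.88 and 3.11) were higher to a like degree. Gtpbp4-ps1 (−3.64, −2.97 and −2.76) and Etnppl (−2.57, −2.23 and −1.89) were lower at each day. In all, 214 genes were higher and 109 lower at every day, where independent lists of these sizes would share 0.399 and 0.152, and 1 gene was called in opposite directions at different days. The day effects share no control arrays, but they share each gene's estimate of the spread. Most calls at each day also lay among clusters above the median mean level. The calls are therefore not independent between days, and the numbers for independent lists are too low a baseline. The log2 differences correlated across 40161 genes with r = 0.68 between day 1 and day 2, 0.58 between day 1 and day 4 and 0.60 between day 2 and day 4, and genes are not independent replicates. The total of 323 was 202 without HPNWT day 1 replicate 2, 151 higher and 61 lower without EGFP day 1 replicate 2, and 206 without EGFP day 4 replicate 1, and it was 1174 with array quality weights. With the negative-control covariate at most 87 could hold at every day, the count called at day 2, and Gtpbp4-ps1 (limma adjusted p = 0.513) and Etnppl (0.263) did not pass at day 2.

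**Figure D3:**
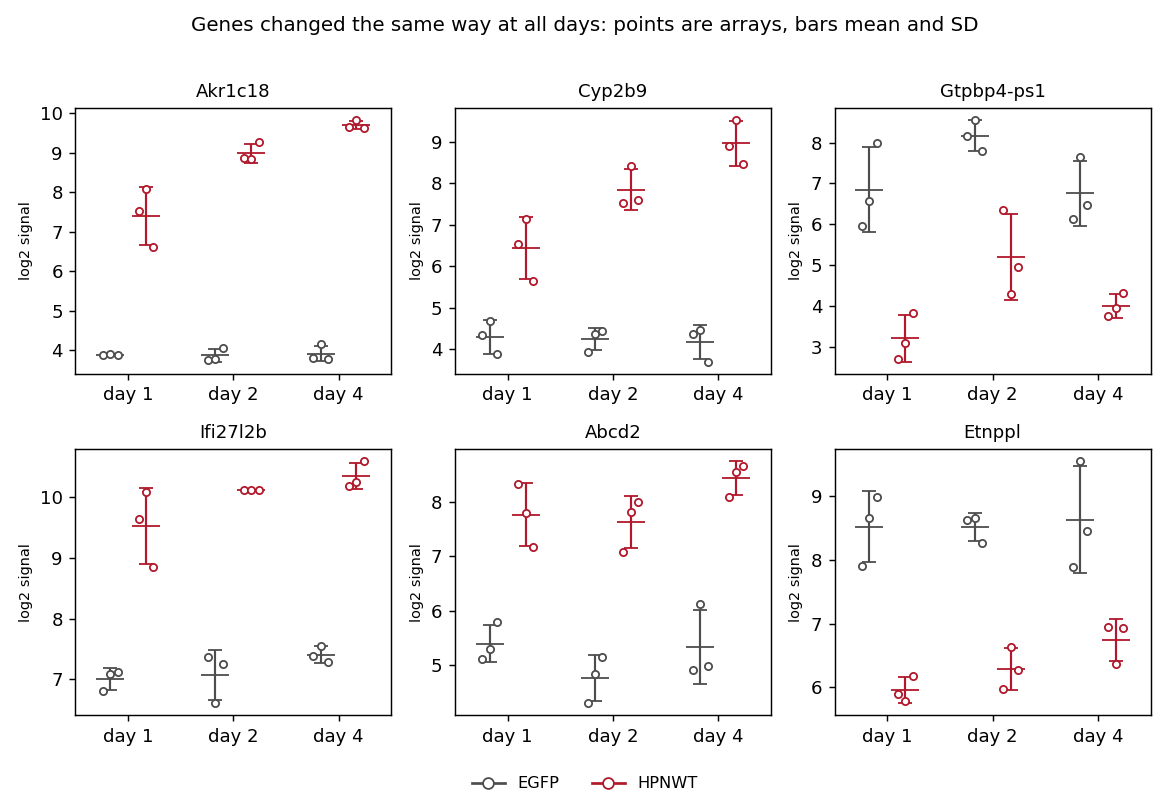
Log2 signal of Akr1c18, Cyp2b9, Gtpbp4-ps1, Ifi27l2b, Abcd2 and Etnppl (vertical axes) for each array, by group and day; points are arrays and bars give the mean and SD of 3 arrays. The HPNWT arrays lie above the EGFP arrays for Akr1c18, Cyp2b9, Ifi27l2b and Abcd2 and below them for Gtpbp4-ps1 and Etnppl at each day.

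The effect of the HPNWT label differed between day 4 and day 1 for Nupr1, Stmn1, Cdkn3 and Mcm6, among others. The stress-induced transcriptional regulator Nupr1 differed by 0.10 log2 at day 1 and 2.06 at day 4, a difference of effects of 1.96 (SE 0.18, limma adjusted p = 3.1e-04). The microtubule regulator Stmn1 (0.81), the cell cycle phosphatase Cdkn3 (1.14) and Mcm6 (1.45) also had larger effects at day 4 (adjusted p = 0.00184, 0.00184 and 0.00504). For Nupr1, Stmn1, Cdkn3 and Mcm6 the HPNWT and EGFP means at both days lay under 6.16. The EGFP means of Cdkn3 (2.52 at day 1 and 2.61 at day 4) lay under the negative-control median. In all, 30 effects were larger and 8 smaller at day 4, with 2298 at an unadjusted p under 0.05. The total of 38 was 23 without HPNWT day 1 replicate 1, 22 and 24 without EGFP day 1 replicate 1 and 2, 22 and 137 without HPNWT day 4 replicate 2 and 3, and 20 and 17 without EGFP day 4 replicate 2 and 3. It was 21 after median centring and 939 with array quality weights. Against day 1, the effect at day 4 was larger for G2/M genes (median 0.50), interferon-stimulated genes (0.52) and S phase genes (0.19), and lower for cholesterol biosynthesis (−0.95) and pericentral genes (−0.28). All 5 lists passed by camera and with an estimated correlation (adjusted p = 0.0403, 0.0188, 0.0403, 0.0403 and 0.0403). Over all genes 4 of 49 G2/M genes, 6 of 47 interferon-stimulated genes and 1 of 43 S phase genes rose and 2 of 25 cholesterol genes fell, against 44, 32, 11 and 20 adjusted over the list alone (where 1 G2/M gene fell), and 3 of 24 pericentral genes fell adjusted over the list alone.

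Between day 4 and day 2, Cdkn3 and the cyclin Ccnb2 were the 2 genes whose effect differed, both larger at day 4. The differences were 1.12 (SE 0.13, limma adjusted p = 0.00739) and 1.87 (SE 0.26, 0.0449), and 2390 genes had an unadjusted p under 0.05. The HPNWT and EGFP means of both genes lay under 6.16 at both days. Those of Cdkn3 in EGFP livers (2.54 at day 2 and 2.61 at day 4) lay under the negative-control median. The interferon regulator Irf7 (1.57) and Nupr1 (1.16) had limma adjusted p = 0.0801 each. The count of 2 ran from 1 to 25 with an array left out, and it was 13, 4 and 25 without HPNWT day 4 replicate 1, 2 and 3. Ccnb2 passed in no fit that left out an array of another group (adjusted p from 0.0622 to 0.231). With array quality weights the count was 47, and with only clusters above the median mean level it was 0. The interferon list differed by a median of 0.56 and held with an estimated correlation (adjusted p = 0.0246), with 0 of 47 members over all genes and 35 adjusted over the list alone. The G2/M list (0.36, 1 of 49 members and 27 adjusted over the list alone) and the cholesterol list (−0.44, 0 of 25 and 1 falling adjusted over the list alone) passed by camera, with adjusted p = 0.295 and adjusted p = 0.651 with an estimated correlation.

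Between day 2 and day 1, limma called 0 genes for a difference of effects, with 2196 at an unadjusted p under 0.05 and 387 called with array quality weights. The count was 1 without HPNWT day 2 replicate 2 and 3 without HPNWT day 4 replicate 3. Mcm6 had the smallest p, with effects of 0.08 at day 1 and 1.40 at day 2 (difference 1.32, SE 0.18, adjusted p = 0.0858). The protease Capn3 (0.63, adjusted p = 0.228), the interferon regulatory factor Irf5 (−0.44, 0.748) and the DNA polymerase gene Pole (0.48, 0.748) followed. By camera the effect was larger at day 2 for S phase genes (median 0.17) and G2/M genes (0.15) and smaller for ribosome biogenesis (−0.33) and cholesterol genes (−0.41), with adjusted p = 0.386, 0.758, 0.504 and 0.758 with an estimated correlation. None of their members was called over all genes, and 7 S phase genes and 1 cholesterol gene were adjusted over the list alone.

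The EGFP livers showed no called change between day 1, day 2 and day 4. The moderated F-test of limma called 0 of 40161 genes, with 1622 at an unadjusted p under 0.05 and 314 called with array quality weights.

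The authors' deposited table for each day was set beside the limma calls. At an FDR under 0.05 the authors' deposited table calls 2184, 2402 and 917 clusters with a symbol at day 1, day 2 and day 4, of which 1677, 1877 and 750 were also called here, all with the same sign. The authors' deposited lists hold 787, 657 and 522 clusters, and 618, 510 and 312 of these have an FDR under 0.05 in the table. The lists follow a fold over 2 and an unadjusted p under 0.05, not the FDR. They are also limited to clusters with a symbol that the authors classed as coding or multiple complex. For Akr1c18 the authors' deposited table gives folds of 55.4, 354 and 971 at day 1, day 2 and day 4. For Hpn it gives −1.17, −1.15 and −1.08, with the authors' FDR at 0.696, 0.569 and 0.882, so no change was called at any day. Across genes, the differences in the value table were 0.462, 0.512 and 0.517 of those in the authors' deposited table (slopes; r = 0.908, 0.926 and 0.864), so folds from the 2 sources are on different scales.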

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

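Chosen only after the results were seen were the tests of complement genes, of growth hormone targets, of immune cell markers and of the negative-control probe sets, and the way of splitting arrays between days. The growth hormone test was divided by day, the value that decides on the background probe sets was changed from a p-value to the lowest day difference, and the pattern of falls was restated for clusters without a symbol, all after values were seen. The bounds for the complement and immune marker tests were later widened by the spread and by signal over background, which turned both from argued against to open, and the growth hormone test of day 1 and day 2 was set to open because its genes are in the list. A pattern of feeding or time of day was dropped before any test.

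The effect of the HPNWT label differed between days for 38 genes (day 4 against day 1) and 2 genes (day 4 against day 2) by a test of the difference itself. For day 4 against day 1 the named genes were Nupr1 (1.96), Stmn1 (0.81), Cdkn3 (1.14) and Mcm6 (1.45), and for day 4 against day 2 Cdkn3 (1.12) and Ccnb2 (1.87). The group means of all these genes on the days compared lay under 6.16. Among the lists whose effect differed by camera were cholesterol biosynthesis, G2/M and S phase for day 2 against day 1 (medians −0.41, 0.15 and 0.17), cholesterol, G2/M, interferon and S phase for day 4 against day 1 (−0.95, 0.50, 0.52 and 0.19), and cholesterol, G2/M and interferon for day 4 against day 2 (−0.44, 0.36 and 0.56). With an estimated correlation the lists for day 4 against day 1 and the interferon list for day 4 against day 2 held, and the others did not, with adjusted p = 0.758, 0.758 and 0.386 for cholesterol, G2/M and S phase for day 2 against day 1, and 0.651 and 0.295 for cholesterol and G2/M for day 4 against day 2. When arrays were moved between both days within HPNWT and within EGFP, 14 of 100 splits gave at least 38 genes (highest other 2248) and 10 of 100 gave at least 2 (highest other 98), so chance is not excluded for either count. For day 2 against day 1 all 100 of 100 splits gave at least the real 0, with 2 as the highest other. Splits that call 2248 and 98 genes, many times the real counts, point to a structure of the samples whose source was not tested. An earlier scheme, which split arrays between HPNWT and EGFP within days, gave 1 of 100 splits for day 4 against day 1 (highest other 33), 11 of 100 for day 4 against day 2 (highest other 1850) and 100 of 100 for day 2 against day 1 (highest other 84).

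Interferon-stimulated and mitotic genes were higher at day 4, where HPNWT day 4 replicate 3 stood apart from its group. Without that array the interferon median was 0.62 (0.58 with it; adjusted p = 0.0146 with an estimated correlation) and the G2/M median 0.39 (0.53 with it; adjusted p = 0.00159 with an estimated correlation), which argues against this array as the whole source of either. Immune cells in the tissue stay open as a source of the interferon rise, since 58 markers of T and NK cells, B cells, neutrophils and monocytes had a pooled median of 0.0043 log2 (quartiles −0.03 and 0.06), but only 1 of them had a mean level above the negative-control 95th percentile of 6.16. A response of liver cells to the HPNWT label may underlie both rises and stays open as a hypothesis, as does a difference between the virus preparations, which was not tested.

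Cyp2b9 was higher in livers labelled HPNWT, and the male-biased list was lower by camera, with adjusted p = 0.378, 0.234 and 0.0767 with an estimated correlation at day 1, day 2 and day 4, and at day 1 not without HPNWT day 1 replicate 1 (adjusted p = 0.0580). Female animals among them are argued against, since no HPNWT array lay further than 0.0825 log2 from the EGFP median of Xist or than 0.309 from that of the mean of 4 Y-linked genes. A general loss of hepatocyte transcripts stays open, since the complement and coagulation median was −0.0553, 0.03 and 0.03 at day 1, day 2 and day 4, against −0.21, −0.38 and −0.38 for male-biased genes, but its members went both ways, with a lower quartile down to −0.21. Weaker growth hormone signalling stays open at day 1 and day 2, where the mean of its targets Igf1, Igfals, Socs2 and Cish differed by −0.87 and −0.69 log2 (exact permutation p = 0.02 over 400 relabellings), since all 4 are themselves in the male-biased list and do not test it. At day 4 the mean differed by −0.0582, less than the SD of 0.390 and 0.361, with Cish at 0.59 and Igf1 at −0.48, and these 3 arrays per group leave it open; the division into days was made after the value over all days (exact permutation p = 0.023) was seen.

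Clusters without a symbol, which no comparison above used, were called at 552, 1773 and 110 clusters at day 1, day 2 and day 4, most of them lower in HPNWT arrays (465, 1596 and 79). A lower nonspecific background on the HPNWT arrays stays open. The GC-count background probe sets were higher at each day, by at least 0.0967 log2, while the negative-control probe sets moved the other way. Values after RMA do not show the raw background, so these probe sets cannot decide it. Less of whatever sequence the negative-control probe sets detect may lie behind the falls, as their median was lower at each day (exact permutation p = 0.00375). With that median as a covariate the day 2 count of genes with a symbol was 87, against 2277 without it, yet 2272 kept their sign, with a median of 75.0% of the difference left and a median SE 1.48 times as large. What these probe sets detect is not known from the files, and the covariate moves with the HPNWT label at day 2.

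No other split of the 6 arrays of a day gave as many genes as the real split at day 1 (1843, highest other 10), day 2 (2277, highest other 0) or day 4 (889, highest other 0), so that 1 of 10 splits was as large at each day. For the gene lists, 2, 3 and 4 of 10 splits gave as many (15, 17 and 21, highest other 16, 18 and 23). At each day another split called more lists than the real grouping, so these camera counts do not tell the HPNWT label from other groupings. With 10 splits a share under 0.05 cannot be reached. For the 323 genes changed the same way at all 3 days, 1 of 100 splits within the days was as large, with 0 as the highest other. Splits that kept the real grouping at more than 1 day were not drawn. Other splits of a single day called at most 10, 0 and 0 genes, so this outcome was nearly fixed in advance and does not exclude chance. For the EGFP livers over time 100 of 100 splits gave at least the real 0, with 3 as the highest other.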

How the results depend on the processing

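Chosen after seeing the data were the fit without both arrays that stand apart, the negative-control covariate and the FDR of the authors' tables. The causes of the changes below were not tested, except that fewer arrays, fewer clusters or other thresholds enter by construction. The replicate numbers do not pair the arrays, as same-number correlations ran from −0.25 to 0.11 and 5 of 18 arrays correlated best with their own number. With the replicate block, 1640, 2178 and 766 genes passed at day 1, day 2 and day 4 and 1 for day 4 against day 2, and the named calls of Rps6 (adjusted p = 0.0647) and Ccnb2 for day 4 against day 2 (0.0526) did not pass. The authors' per-array values could not be tried, since their tables give group averages.

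Counts at day 1, day 2 and day 4 were 723, 3888 and 149 from the 6 arrays of a day. They were 8116, 8260 and 2363 with array quality weights, which also gave 387, 939 and 47 genes for day 2 against day 1, day 4 against day 1 and day 4 against day 2, 314 in EGFP over time and 1174 the same way at all days. An unadjusted p under 0.05 with a fold of at least 1.5, in place of the adjusted p, gave 939 and 1214 genes at day 1 and day 2, while a fold of at least 2 gave 194, 269 and 172, and 50 the same way at all days. An adjusted p under 0.1 gave 2829 and 3663 at day 1 and day 2, and 569 the same way. All clusters gave 4029 at day 2 and 1 for day 4 against day 2. Median centring gave 21 for day 4 against day 1 and 1 for day 4 against day 2. Without dim clusters the last count was 0, and r between days was 0.75, 0.64 and 0.66. Without both arrays that stand apart there were 4158 genes at day 2, 86 for day 4 against day 1 and 26 for day 4 against day 2, and r with day 4 was 0.53 for day 1 and 0.69 for day 2. The covariate gave 1097 and 87 genes at day 1 and day 2 and 1 for day 4 against day 2. Lists passing were 1, 0 and 5 with an estimated correlation, and 7 and 10 by fry at day 1 and day 2. The FDR of the authors' tables gave 2184, 2402 and 917 genes.

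Directions turned for Hpn at day 2 after quantile normalization (0.0538) and at day 4 with array weights (−0.0620) and without both arrays (−0.0554). They also turned for Capn3 (0.0170) and Pole (0.0350) at day 1 after quantile normalization, for Pole after centring (0.0155), and for stellate markers at day 4 without both arrays (−0.0306). With array weights the stellate test turned while its median stayed above 0 (0.00920). The PPARα median at day 2 was above 0 after quantile normalization (0.00844) and with the covariate (0.00151), while the test still pointed lower. With the covariate Stab2 (0.22), gluconeogenesis (0.050) and sinusoidal markers (0.14) turned at day 2.

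With 1 array left out, where the remaining pair is assumed to vary like the other groups, counts ran from 858 to 2993, 791 to 3487 and 528 to 1016 at day 1, day 2 and day 4. They ran from 0 to 3, 17 to 137 and 1 to 25 for the differences between days, from 202 to 423 for the same way at all days and from 0 to 0 in EGFP. Hpn ran from −0.17 to 0.0167, −0.10 to −0.06 and −0.0554 to 0.20, stellate markers at day 4 from −0.0306 to 0.300, r from 0.60 to 0.72, 0.51 to 0.59 and 0.46 to 0.69, and lists from 14 to 20, 13 to 19 and 18 to 24. Of the other values for single genes and lists, 1757 kept direction and side of the threshold, 165 no longer passed, 26 newly passed and 8 turned. With 1 array left out these were 3280, 88, 15 and 1. Signal over background also limits the arrays, as the 95th percentile of the negative controls averaged 6.16 log2, above the median of the clusters.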

Other observations

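The genes named in this part were chosen only after the results were seen, while the lists were fixed earlier.

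Complement and coagulation genes changed in both directions without a shift of the list. Of 34 members 8 rose and 3 fell at day 2 (8 and 4 adjusted over the list alone; camera adjusted p = 0.828), and 5 rose and 3 fell at day 4 (8 and 5 adjusted over the list alone; adjusted p = 0.318). The antiplasmin gene Serpinf2 was higher by 0.64, 0.62 and 0.55 log2 at day 1, day 2 and day 4 and the coagulation factor gene F11 by 1.11, 1.06 and 0.99, while the mannose-binding lectin gene Mbl1 was lower by −0.81, −0.92 and −1.10, all passing limma's adjusted p and named after their values were seen. Fatty acid synthesis genes did not pass as a list (adjusted p = 0.175, 0.1 and 0.0556), yet Acaca, the acetyl-CoA carboxylase gene, was higher at each day (0.65, 0.75 and 0.64) and its activator gene Mlxipl lower at day 1 and day 2 (−0.82 and −0.69), also named after their values were seen.

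Markers of T and NK cells (camera adjusted p = 0.915, 0.870 and 0.867), B cells (0.821, 0.295 and 0.990) and neutrophils (0.684, 0.493 and 0.164) did not pass at day 1, day 2 or day 4, and for T and NK cells the median and the mean differed in sign at day 1 and day 4. Array quality weights, which limma estimated from the fit, were lowest for HPNWT day 4 replicate 3 (0.142) and HPNWT day 1 replicate 1 (0.340) and highest for EGFP day 1 replicate 2 (6.51).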
